A study of Mus musculus with 14 samples.

How the data were processed

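RNA sequencing was done on 14 samples in 7 groups of 2, all from mice: Ter cells (Ter-119+ CD45- Lin-) of the spleen of tumour-bearing mice, their CD45+ Ter-119- spleen control, Ter cells of embryonic liver (E14.5), and HSC, CLP, MEP and CMP of the bone marrow of wild type mice. The labels state a purity above 98% after sorting and libraries made from total RNA, and name only the genome build, mm10; the aligner, the counter and the annotation are not given in the sources used here.

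The deposited table holds 1 column per group, with values in FPKM made by the authors as the mean of the group's 2 samples. The planned analysis assumed values per sample, which the file does not hold. Of its 49588 lines, 2 have no gene name and 3 are identical repeats, which leaves 49583 genes; 49324 of them were matched by ID to GENCODE M21 (GRCm38), which gave symbols, types and coordinates, and 259 were not. The unit was read from the values. The columns come in 2 number formats. In spleen Ter, liver Ter, MEP and CMP, between 89.6% and 92.1% of low values times the gene's exon length fell on whole multiples of a step per fragment (within a tolerance of 0.005), and processed pseudogenes held 0.44% to 1.52% of FPKM. In the control, HSC and CLP, 4.4% to 5.3% did, and processed pseudogenes held 6.1% to 8.02%. The 2 sets of columns were thus not made alike, and comparisons across them were not tested.

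In the first set each mean is the average of 2 values, each a whole number of fragments times its library's step, so the 2 libraries of each group could be recovered. The steps and depths were found from low values, and each gene's pair of fragment counts from its mean, with the annotated exon length for 11280 genes and a length found from the steps for 2357; for 412 no length gave whole numbers. Of 14049 genes with a mean of at least 1 FPKM in any of these 4 columns, 13547 (96.4%) were recovered in all 8 libraries. The means of the recovered values matched the deposited means within 4.7e-07 of their size. The method accepts only counts that give such a match, so this is no separate check. The most abundant genes, among them S100a9, Hbb-bs and Hba-a1, could not be recovered in the groups where they were high, and the recovered genes hold 31.9% to 59.8% of each library's fragments. Tested on simulated data, the method found all 8 steps, recovered 99.2% of genes, and gave a wrong count in a library for 12 of 27795 recovered genes (0.043%). When 1000 genes were given a wrong length, 94.0% were still recovered through the length search. The simulated genes were those for which a length had been found, and followed the model that the method assumes. The error on real genes that depart from that model was not measured. This method was chosen after the data were seen. Values from the control, HSC and CLP columns are the authors' means and have no error.

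The 4 comparisons within the first set (spleen Ter with liver Ter, MEP and CMP, and MEP with CMP) were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with trend) on log2(FPKM + 1) of the 8 libraries, with 1 coefficient per group and 1 shared estimate of the spread (4 residual and 2.6 prior degrees of freedom). The 12746 genes with at least 1 FPKM in 2 libraries were tested. A gene was called with a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. On libraries simulated from the genes' mean levels, with a dispersion of 0.05, 10% of genes changed 2-fold were called, 82% of those changed 4-fold, 90% of those changed 8-fold and 96% of those changed 16-fold, and 15 of 154 calls were unchanged genes. The rate for genes changed 2-fold is held down by the call itself, which needs an estimated log2 fold change of at least 1. A spread as wide as that between the spleen Ter libraries was not simulated. The model's p-values with 2 libraries per group rest on the shared estimate of the spread. For each gene that estimate pools the 4 groups, though the spleen Ter libraries differed most from each other. Where a gene differs between them, the SE and p-value can be too small for spleen Ter comparisons. For MEP against CMP they can be too large. The 37 gene lists (603 genes in all, 11 of them without a value, not analysed here) and the genes the report names were set by rule before the data were examined, as were the tests, thresholds and alternatives. Lists with at least 3 tested genes were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted by Benjamini-Hochberg over all lists and comparisons.

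The rule names, for spleen Ter against the control, liver Ter and MEP and for MEP against CMP, the 10 genes in each direction with the largest changes, at least 5 FPKM in each library of the higher group and libraries that do not overlap, passing over unnamed gene models and antigen receptor segments, and any list member. Against the control, which has no test and no recovered libraries, that rule could not be applied as set. There a mean of at least 5 FPKM in the higher group and a change of at least 2-fold stood in for it. Not every gene the rule allows is reported here. Which list members serve as examples was chosen after their values were seen, and so were Nr4a1, Ier2, Hlf and the Y-linked genes where they are printed. For spleen Ter against the control, HSC and CLP, fold changes of log2(mean + 1), counts of genes at least 2-fold apart and list medians are given, with each median's percentile among 10000 random lists of genes matched in expression over 20 bins. The floor of 3 fragments per library stands in for genes at 0 in both libraries of a group in list medians given with the floor, and covers counting error only. Computations other than limma used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.

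Alternatives were a pseudocount of 0.1, no filter, a filter of 5 FPKM, median-of-ratios scaling, quantile normalization, totals without globin genes, a fit of only the 4 libraries compared, no trend, and leaving out each of the 8 recovered libraries. For the similarity they were also Spearman's rho and leaving out erythroid list genes. Added after the data were seen were limma-voom on the recovered fragments and, for the comparisons of means, protein-coding genes only.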

Results

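RNA sequencing measured gene expression in Ter cells, which carry the erythroid surface antigen Ter-119 and lack CD45 and lineage markers, sorted from the spleen of tumour-bearing C57BL/6 mice. The 14 samples form 7 groups of 2. Beside the spleen Ter cells there were CD45+ Ter-119- spleen cells of tumour-bearing mice as the control, and Ter cells taken with the same gate from embryonic liver (E14.5). The other 4 groups were bone marrow populations of wild type mice: hematopoietic stem cells (HSC), common lymphoid progenitors (CLP), megakaryocyte-erythroid progenitors (MEP) and common myeloid progenitors (CMP). The deposited table gives 1 value per gene and group, the authors' mean FPKM (fragments per kilobase of transcript, scaled to library size), for 49583 genes, with no error. Of these, 11500 genes had a mean of at least 1 FPKM in spleen Ter, 7240 in liver Ter, 12311 in the control, 12980 in HSC, 12958 in CLP, 9921 in MEP and 11243 in CMP.

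For spleen Ter, liver Ter, MEP and CMP, the 2 libraries behind each mean were recovered from the digits of the means; they are called A, the deeper, and B, and carry no replicate number. Their depths were 15110000 and 14550000 fragments in spleen Ter, 28540000 and 17540000 in liver Ter, 24620000 and 20080000 in MEP, and 14640000 and 13410000 in CMP. The depths of the control, HSC and CLP samples are unknown. Nothing states that the 2 samples of a group came from separate animals, so each p-value below measures the spread between samples only. The 2 spleen Ter libraries differed from each other more than those of the other 3 groups did: 22.2% of 12746 tested genes differed by more than 2-fold between them, against 0.6% in liver Ter, 1% in MEP and 2% in CMP. Pearson's r across genes, which are not independent replicates, was 0.896 between the spleen Ter libraries, 0.993 in liver Ter, 0.988 in MEP and 0.98 in CMP.

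**Figure D1:**
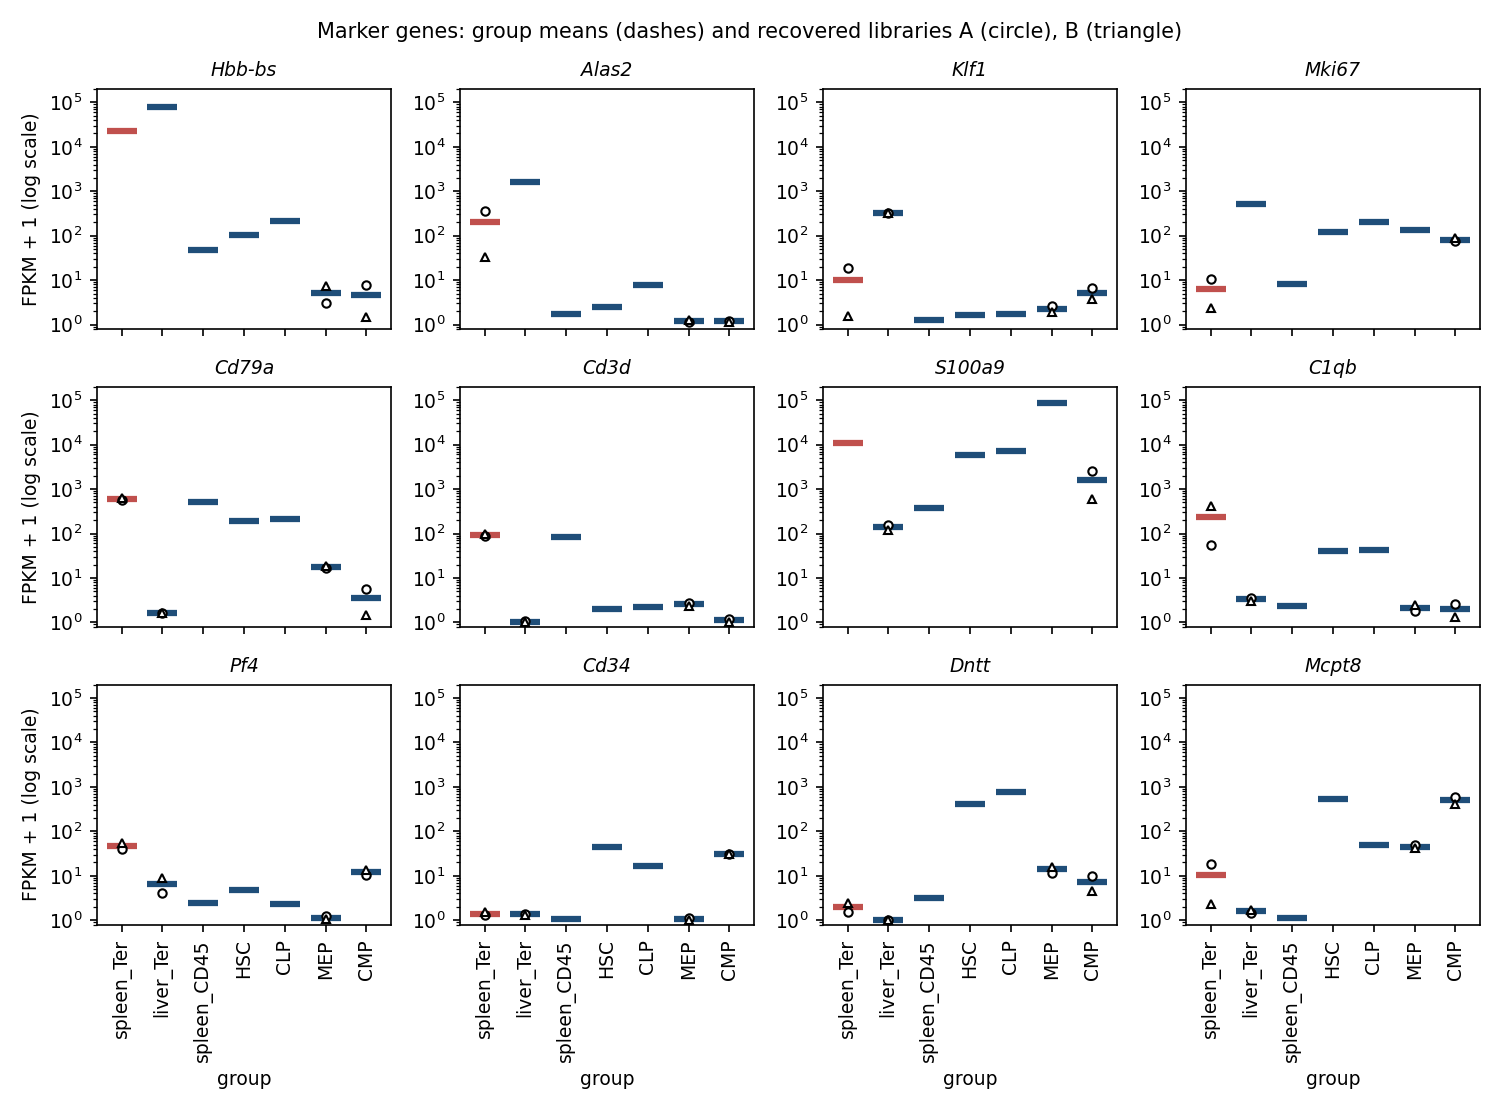
Expression of 12 marker genes in the 7 groups, as FPKM + 1 on a log axis; dashes are the authors' group means, circles and triangles the recovered libraries A and B where the gene was recovered. In spleen Ter, Alas2 was 366 FPKM in library A and 32.3 in library B, while Cd79a was 555 and 626.

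The first comparison asked how spleen Ter cells differ from the CD45+ cells of the same organ. Spleen Ter cells held red cell transcripts that the control all but lacked. The mean FPKM of the adult beta-globin gene Hbb-bs (ENSMUSG00000052305, mm10 chromosome 7, 103826534 to 103828096) was 22390 in spleen Ter and 45.7 in the control, and that of the alpha-globin gene Hba-a1 (ENSMUSG00000069919, chromosome 11, 32283511 to 32284465) was 15630 against 75.02. The 6 adult globin genes with values made up 13.7% of all FPKM in spleen Ter and 0.06% in the control. Alas2, the first enzyme of erythroid heme synthesis (ENSMUSG00000025270, chromosome X, 150547375 to 150570638), had a mean of 199 against 0.689 FPKM.

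Red cell membrane and heme genes were higher in library A of spleen Ter than in library B; for Hbb-bs and Hba-a1 the split between the libraries was not recovered. The 2 adult globin genes that were recovered, both far below Hbb-bs in level, had a median of 19.8 FPKM in library A and 0.05 in library B. Over them the median log2 fold change from the control was -0.17 without library A and 3.32 without library B. Alas2 was 366 FPKM in library A and 32.3 in library B. Slc4a1, the red cell anion exchanger, was 44.3 in library A and 2.07 in library B, around the control's 2.56, so that its log2 fold change was 2.76 from the mean and -0.22 without library A. In the red cell membrane list, 10 of 15 genes were at least 2-fold higher in spleen Ter and none lower, with a median log2 fold change of 1.42. Over the recovered genes that median was -0.12 without library A and 2.33 without library B. For heme synthesis it was 8 of 11 genes and a median of 1.38, which was 0.61 without library A and 1.67 without library B. The erythroid transcription factors went both ways, with 7 of 18 genes higher and 4 lower, a median of -0.40 and a mean of 0.16; the median was 0.04 after quantile normalization.

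Myeloid and platelet transcripts were also higher in spleen Ter than in the control. The alarmin gene S100a9 (ENSMUSG00000056071, chromosome 3, 90692632 to 90695721) averaged 10970 against 369 FPKM, and all 15 neutrophil genes were at least 2-fold higher, with a median log2 fold change of 4.89. Over the 10 recovered genes of that list it was 3.20 without library A and 4.48 without library B. Retnlg, a resistin-like neutrophil gene, was 1269 and 1155 FPKM in the 2 libraries against 3.27. The chemokine gene Cxcl2 was 492 and 143 against 1.38, and Stfa2l1, a stefin gene of neutrophils, was 133 and 115 and is listed at 0 in the control. The macrophage and monocyte list had 19 of 21 genes higher and a median of 2.54, or 3.07 without library A and 1.15 without library B. Its complement gene C1qb was 54.6 FPKM in library A and 414 in library B, against 1.29 in the control. In the megakaryocyte and platelet list 12 of 17 genes were higher and 1 lower, with a median of 2.04, or 1.88 without library A and 1.39 without library B over the recovered genes; Pf4, platelet factor 4, was 38.8 and 53.7 against 1.49. The medians of these 3 lists and of the red cell membrane and heme lists lay at percentile 100, after rounding, of the 10000 random lists of matched expression. Random genes were drawn independently, while genes of a list can vary together, so the percentile is no test. It also uses the mean of both libraries, though the red cell lists were higher in library A.

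Lymphocyte transcripts were present in spleen Ter, with most genes of the B and T cell lists near or below the control's level. Immunoglobulin genes were 9.38% of FPKM in spleen Ter and 4.78% in the control. The B cell receptor chain gene Cd79a (ENSMUSG00000003379, chromosome 7, 24897381 to 24902197) was 555 and 626 FPKM against 502.5 in the control, and the T cell receptor complex gene Cd3d (ENSMUSG00000032094, chromosome 9, 44981786 to 44987339) was 85.1 and 98.6 against 81.1. The B cell list had a median log2 fold change of -1.01, at percentile 11 of the random lists, and the T cell list -0.55, at percentile 34, with 9 of 18 and 8 of 23 genes at least 2-fold lower and 0 and 1 higher. Without library B these medians were -1.51 and -0.95. Within them the B cell transcription factor gene Pax5 was 4.52 and 6.03 against 299, Ms4a1 was 53.3 and 55.3 against 267, and Cd4 was 2.36 and 12.0 against 78.6. Among genes of immune suppression, the arginase gene Arg2 averaged 6.95 against 0.0332 FPKM, while Cd274, which encodes PD-L1, averaged 12.2 against 51.1; 5 of the 14 genes in that list were higher and 1 lower, with a median of 0.70, or 1.19 without library A and 0.45 without library B.

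Over 13835 genes, 1865 had a mean at least 2-fold higher in spleen Ter and 3927 at least 2-fold lower, with a median log2 fold change of -0.32. The higher share of the 2-fold genes was 32.2%, and 48.0% with median-of-ratios scaling, 51.1% with quantile normalization and 42.9% with totals that leave out globin genes. No test was made here or against HSC and CLP, because those 3 columns were made by another procedure than the spleen Ter column and hold no recoverable libraries. Genes far below the control included some that were high in all 3 of those columns and low in the other 4. The mitochondrial gene mt-Atp8 was 0.162 FPKM in spleen Ter, 1.86 in liver Ter, 0.0996 in MEP and 0.716 in CMP, against 3282 in the control, 7136 in HSC and 4753 in CLP. Rpl24 was 2.01 in spleen Ter, 0.106 in liver Ter, 0.434 in MEP and 1.12 in CMP, against 818 in the control, 722 in HSC and 738 in CLP.

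The second comparison set spleen Ter cells against embryonic liver cells of the same gate, a tissue of normal fetal erythropoiesis. Erythroid genes were far lower in spleen Ter. All 11 tested genes of the red cell membrane list fell, with a median log2 fold change of -5.16 (camera, Benjamini-Hochberg adjusted p = 2.54e-09, and 0.582 with an estimated correlation). Kel, the Kell blood group protein (ENSMUSG00000029866, chromosome 6, 41686330 to 41704339), was 660 and 633 FPKM in the liver libraries and 12.4 and 0.0496 in spleen Ter libraries A and B. Its log2 fold change was -7.43 ± 1.03 (SE, limma, Benjamini-Hochberg adjusted p = 0.000754). All 9 heme synthesis genes fell, with a median of -4.27 (adjusted p = 1.26e-08 by camera, 0.582 with an estimated correlation). Among them Cpox was 20.4 and 6.73 against 639 and 631 FPKM. Of 17 erythroid transcription factors 14 fell (median -3.73, adjusted p = 7.48e-10 by camera, 0.582 with an estimated correlation). Klf1, the erythroid Kruppel-like factor (ENSMUSG00000054191, chromosome 8, 84901928 to 84905291), was 17.5 and 0.584 against 319 and 315 FPKM, and Gata1 was 4.97 and 1.07 against 106 and 104. Tal1 was 1.77 and 2.01 against 141 and 141, and the erythropoietin receptor gene Epor was 3.69 and 2.87 against 135 and 131.

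The largest falls from liver Ter also included the red cell pyruvate kinase Pklr (-6.40 ± 0.23), the nucleotide enzyme Gmpr (-7.23 ± 0.31), hemogen, Hemgn (-7.01 ± 0.59) and the embryonic globin gene Hbb-bh1 (-7.05 ± 0.17), in limma log2 fold changes with SE. The erythroblast membrane gene Ermap changed by -6.47 ± 1.00. Pklr was 0.184 and 0.0213 FPKM against 94.3 and 89.5. Bpgm, the red cell mutase that tunes oxygen release from hemoglobin, was 185 and 12.8 FPKM against 204 and 206 and did not pass (log2 fold change -2.02 ± 1.04, limma, Benjamini-Hochberg adjusted p = 0.126). Of 15 reticulocyte maturation genes 9 fell (median -2.37, adjusted p = 1.12e-06 by camera, 0.582 with an estimated correlation). Of 8 fetal genes 4 fell and 1 rose (median -0.80, adjusted p = 0.00149, 0.582 with an estimated correlation). With a filter of 5 FPKM that list did not pass and its median was 0.12 (adjusted p = 0.312). The imprinted growth gene H19 was 0 in both spleen Ter libraries against 4.33 and 5.77 FPKM. Of 6 hepatocyte genes 2 fell (median -0.66, adjusted p = 0.00418, 0.620 with an estimated correlation), one of them the fetal serum protein gene Afp at 1.34 and 1.45 against 4.36 and 6.28 FPKM. In the antioxidant list 6 of 13 genes fell and 1 rose (median -0.62, adjusted p = 0.00169, 0.582 with an estimated correlation). With median-of-ratios scaling, quantile normalization and totals that leave out globin genes the fetal median was -1.34, -1.64 and -1.15, the hepatocyte median -1.52, -1.74 and -1.24, and the antioxidant median -1.77, -1.46 and -1.40. The erythropoietin receptor pathway had 6 of 12 genes down and 5 up (median -0.81, adjusted p = 0.0226, 0.632 with an estimated correlation). It did not pass with median-of-ratios scaling (0.191), quantile normalization (0.307), totals that leave out globin genes (0.0753) or a filter of 5 FPKM (0.0852). Iron uptake passed as lower, with 4 of 12 down and 1 up, or 4 and 0 adjusted over the list alone (median -0.07, adjusted p = 0.014, 0.582 with an estimated correlation, and 0.0737 without spleen Ter library A). Its median was -1.21 with median-of-ratios scaling, -0.98 with quantile normalization and -0.84 with totals that leave out globin genes.

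Cell division genes were lower in spleen Ter than in liver Ter, though not than in the control, where 6 of 26 had a mean at least 2-fold higher in spleen Ter and 3 lower (median 0.45, or -0.39 without library A). All 26 tested genes of mitosis and DNA replication fell, with a median log2 fold change of -3.21 (camera, Benjamini-Hochberg adjusted p = 2.80e-19, 0.582 with an estimated correlation). The topoisomerase gene Top2a (ENSMUSG00000020914, chromosome 11, 98992943 to 99024189) was 5.32 and 1.66 FPKM against 65.4 and 68.3, a change of -4.05 ± 0.38 (limma, Benjamini-Hochberg adjusted p = 0.000139). The nucleotide reductase subunit Rrm2 was 28.3 and 6.65 against 319 and 327 FPKM, and the helicase subunit Mcm5 10.99 and 6.65 against 53.7 and 52.8.

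Genes of immune cells were the other side of this comparison. All 17 B cell genes rose, with a median log2 fold change of 5.42, as did all 23 T cell genes, with 4.37, and all 13 NK cell genes, with 2.76. The lists passed in camera (Benjamini-Hochberg adjusted p = 1.10e-05, 7.43e-07 and 0.00315, each 0.658 with an estimated correlation). The T cell median was 4.27 with the 9 genes at 0 in both liver libraries set to a floor of 3 fragments per library. Cd79a was 555 and 626 FPKM against 0.601 and 0.587, a log2 fold change of 8.53 ± 0.55 (limma, Benjamini-Hochberg adjusted p = 3.03e-05), and Cd3d was 85.1 and 98.6 against 0.0579 and 0. The largest rises included Ly6d, a lymphoid surface gene (9.44 ± 0.43), the chemokine gene Ccl5 (8.79 ± 0.29), the interleukin gene Il1b (8.31 ± 0.89) and the antibody joining chain Jchain (8.17 ± 0.42), in limma log2 fold changes with SE. With them went the lymphocyte quiescence factor Klf2 (8.03 ± 0.18), the leukocyte antigen Cd52 (7.82 ± 0.21) and Wfdc17 (8.09 ± 0.50). Jchain was 0 in both liver libraries. All 6 tested genes of MHC class II presentation rose (median 6.04, adjusted p = 0.00277, 0.620 with an estimated correlation), with H2-DMb2 at 201 and 226 FPKM against 0.0615 and 0.0334. So did all 8 of MHC class I presentation (median 4.65, adjusted p = 0.00504, 0.676 with an estimated correlation).

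Myeloid genes were higher as well, less evenly over the 2 spleen Ter libraries. All 6 tested neutrophil genes rose with a median of 5.23, and 14 of 16 macrophage and monocyte genes with a median of 2.87 (15 adjusted over the list alone), but neither list passed in camera (Benjamini-Hochberg adjusted p = 0.118 and 0.0626). Ly6g was 102 and 16.3 FPKM in libraries A and B against 0.223 and 0.0605, and C1qb was 54.6 and 414 against 2.54 and 2.10. Of 14 myeloid progenitor genes 11 rose (median 3.66, adjusted p = 0.00392, 0.582 with an estimated correlation, and 0.207 without spleen Ter library A). Of 12 genes of immune suppression 10 rose, with a median of 2.58, or 2.51 with the floor (camera adjusted p = 0.0226, 0.663 with an estimated correlation, and 0.0658 without library A). Among them the interleukin gene Il10 was 3.59 and 7.45 FPKM and 0 in both liver libraries, and Cd274 was 10.8 and 13.6 against 0.0871 and 0.110. Arg2 was 10.3 and 3.61 against 0.0736 and 0.0799, and the galectin gene Lgals9 was 47.0 and 66.5 against 1.62 and 2.32. Of 11 sort marker genes 9 rose (median 4.62, adjusted p = 0.0145, 0.620 with an estimated correlation, and 0.0672 without library A).

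In limma 5478 of 12746 genes rose and 1468 fell between liver Ter and spleen Ter (Benjamini-Hochberg adjusted p under 0.05 and at least 2-fold). The globins alone held 47.5% of liver Ter FPKM, and the median log2 fold change of all genes was 0.79. Relative to that median the red cell membrane list stood at -5.95, mitosis and DNA replication at -4.00, B cell genes at 4.63 and T cell genes at 3.58. Rises made up 78.9% of called genes, and 53.6% with median-of-ratios scaling, 49.0% with quantile normalization and 61.8% with totals that leave out globin genes. Camera called 18 of 34 lists at the preset correlation and 0 with an estimated correlation, where 6 had an unadjusted p under 0.05. Fold changes are of FPKM + 1, which understates those of genes near 0.

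**Figure D2:**
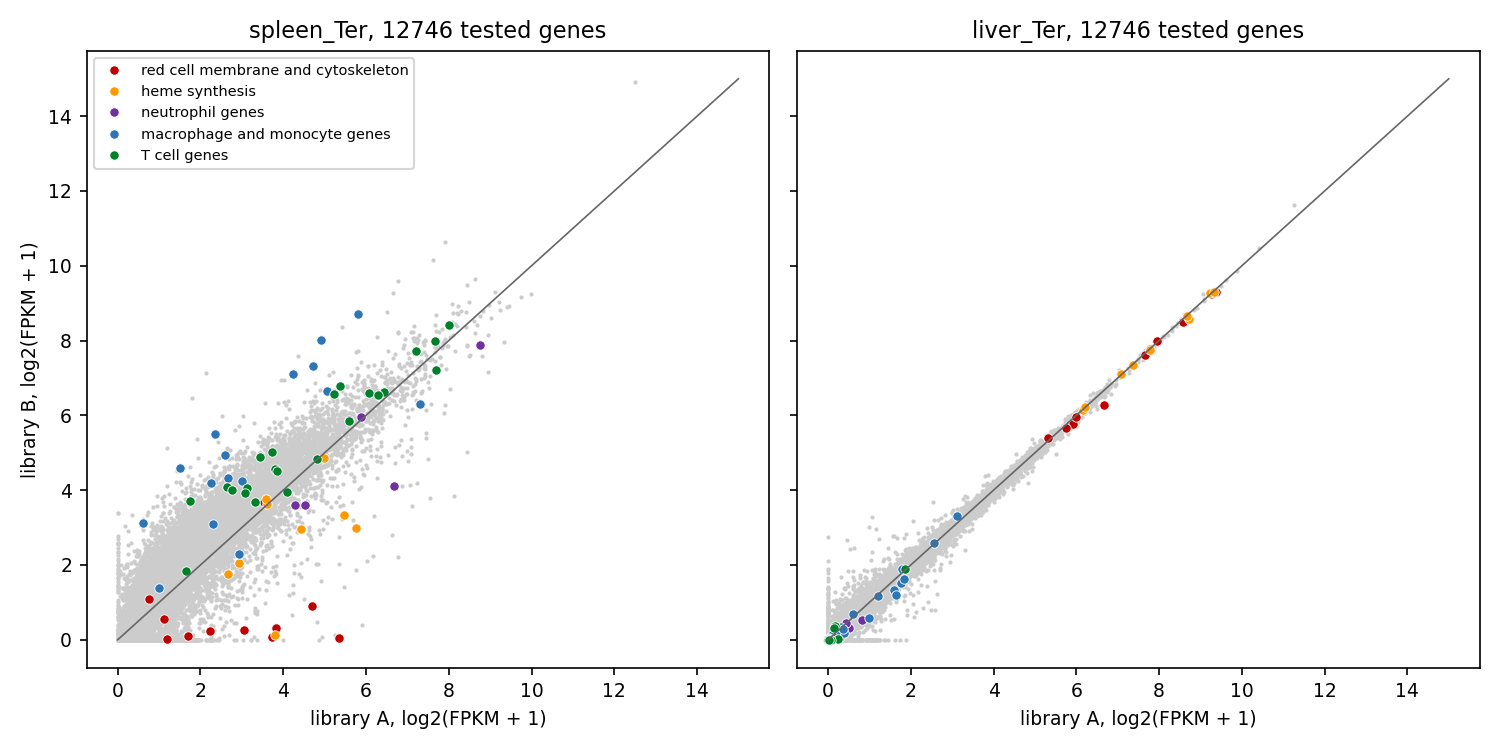
Expression of 12746 tested genes in library A (horizontal axis) against library B (vertical axis) of spleen Ter (left) and liver Ter (right), as log2(FPKM + 1), with the line of equality; coloured points are genes of 5 lists. In spleen Ter red cell membrane genes lie below the line, with a median log2 ratio of A to B of 1.83 over 17 recovered genes, and macrophage and monocyte genes above it, with -2.35 over 19.

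The third comparison asked how far spleen Ter cells differ from MEP, the progenitor nearest to the red cell lineage by name. The neutrophil list made up 48.1% of FPKM in this MEP column, and Gata1 was 1.18 and 0.674 FPKM in its libraries. Spleen Ter again held lymphocyte genes that the other group had at low level. All 23 T cell genes rose (median log2 fold change 4.19, camera, Benjamini-Hochberg adjusted p = 6.60e-11, 0.589 with an estimated correlation). So did 16 of 17 B cell genes (4.17, adjusted p = 1.34e-07, 0.658 with an estimated correlation) and 8 of 13 NK cell genes (1.94, adjusted p = 0.00169, 0.658 with an estimated correlation). The largest rises were those of Jchain (7.99 ± 0.42), the cytotoxic T cell coreceptor chain Cd8b1 (7.41 ± 0.21), Ly6a, which encodes Sca-1 (7.21 ± 0.27), Ly6d (6.85 ± 0.43) and the homing receptor gene Ccr7 (6.59 ± 0.28), in limma log2 fold changes with SE. Cd8b1 was 205 and 148 FPKM against 0.0548 and 0 in the MEP libraries, and Ccr7 was 181 and 118 against 0.534 and 0.529. The 6 MHC class II genes rose (median 4.39, adjusted p = 0.00025, 0.582 with an estimated correlation), with H2-DMb2 at 5.25 ± 0.15. Also higher were 5 of 8 class I genes (1.37, adjusted p = 0.0226, 0.680 with an estimated correlation, and 0.0882 without spleen Ter library B). The same held for 6 of 10 dendritic cell genes (1.39, adjusted p = 0.0165, 0.658 with an estimated correlation, and 0.109 without library A).

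Cell division genes and some granulocyte genes were lower in spleen Ter than in MEP. Of 26 genes of mitosis and DNA replication 24 fell, or 25 adjusted over the list alone, with a median of -2.39 (camera, Benjamini-Hochberg adjusted p = 7.48e-10, 0.582 with an estimated correlation). Top2a was 5.32 and 1.66 FPKM against 66.2 and 87.5 (-4.23 ± 0.38, limma, Benjamini-Hochberg adjusted p = 0.000197) and Mcm5 was 10.99 and 6.65 against 57.3 and 62.8. The largest falls included the septin gene Sept5 (-6.78 ± 0.52), the granulocyte integrin gene Itgb2l (-6.62 ± 1.13), ficolin B, Fcnb (-5.23 ± 1.09), the vinculin gene Vcl (-5.14 ± 0.17) and the granulocyte transcription factor gene Cebpe (-5.10 ± 0.77), in limma log2 fold changes with SE. Cebpe (ENSMUSG00000052435, chromosome 14, 54710360 to 54712174) was 19.7 and 2.39 FPKM in spleen Ter against 275 and 299. Of 14 myeloid progenitor genes 8 fell and 2 rose (median -2.06, adjusted p = 0.0391, 0.582 with an estimated correlation, 0.124 without spleen Ter library B and 0.051 without MEP library A). Of 8 mast cell and basophil genes 5 fell, or 6 adjusted over the list alone (median -1.71, adjusted p = 0.0382, 0.666 with an estimated correlation, 0.111 without spleen Ter library B and 0.0512 without MEP library B). The neutrophil list did not pass (3 of 6 genes lower and 1 higher, 5 lower and 1 higher adjusted over the list alone, median -2.27, adjusted p = 0.210). The vascular and stem cell factor Erg was 0.936 and 0.0198 FPKM in spleen Ter against 30.5 and 25.6 in MEP (-4.36 ± 0.31, limma, Benjamini-Hochberg adjusted p = 8.41e-05).

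None of the erythroid lists that could be tested passed between spleen Ter and this MEP column. The adult globins, with only 2 genes recovered, were not tested. Their group means summed to 51458.5 FPKM in spleen Ter and 8.9 in MEP. None of the erythroid transcription factors rose and 5 of 17 fell; their median was 0.66, their mean -0.09, and camera's direction was down (Benjamini-Hochberg adjusted p = 0.898). Gata1 was 4.97 and 1.07 FPKM against 1.18 and 0.674, and Klf1 was 17.5 and 0.584 against 1.57 and 0.944. In heme synthesis 3 of 9 genes rose and none fell (median 1.28, adjusted p = 0.242), one of them Alad, the second enzyme of the pathway, at 30.7 and 28.1 FPKM against 2.084 and 1.996. The red cell membrane list had 1 gene up and 1 down of 11 (median 0.94, adjusted p = 0.488). Some platelet genes were higher in both spleen Ter libraries, though their list did not pass. Pf4 (ENSMUSG00000029373, chromosome 5, 90772435 to 90773383) was 38.8 and 53.7 FPKM against 0.225 and 0.0691 (5.35 ± 0.38, limma, Benjamini-Hochberg adjusted p = 8.82e-05). The chemokine gene Ppbp was 17.1 and 24.7 against 0.113 and 0. The megakaryocyte and platelet list had 10 of 17 genes higher and 3 lower (median 1.25, adjusted p = 0.174). Oxidative phosphorylation genes rose in 8 of 23 (median 0.63, adjusted p = 0.00207, 0.582 with an estimated correlation), with Ndufa2 at 166 and 247 FPKM against 47.5 and 45.9. Ribosomal protein genes rose in 7 of 14 and fell in 2 (median 1.00, adjusted p = 0.021, 0.589 with an estimated correlation, and 0.119 without spleen Ter library A). Only 17 of 79 such genes were recovered, mostly not the abundant ones, with medians of 8.91 and 6.41 FPKM in spleen Ter libraries A and B. Over all 79 the median of the group means was 211.73 FPKM in spleen Ter and 108.27 in MEP, which was not tested. Hepatocyte genes rose in 3 of 6 (median 1.02, or 0.95 with the floor, adjusted p = 0.0231, 0.658 with an estimated correlation, and 0.0735 without library A). In all, 2967 genes rose and 2464 fell in limma, and camera called 12 of 34 lists at the preset correlation and 0 with an estimated correlation, where 0 had an unadjusted p under 0.05.

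The fourth comparison set spleen Ter cells against CMP, the bone marrow progenitor of myeloid and erythroid cells. Lymphocyte genes were again higher in spleen Ter. All 17 B cell genes (median log2 fold change 4.65), all 23 T cell genes (4.12) and 12 of 13 NK cell genes (2.46) rose. The lists passed in camera (Benjamini-Hochberg adjusted p = 3.19e-13, 1.18e-17 and 1.01e-07, each 0.582 with an estimated correlation). Cd79a changed by 7.70 ± 0.55, Cd3d by 6.38 ± 0.19 and the granzyme gene Gzma by 4.66 ± 0.39 (limma log2 fold changes with SE; Benjamini-Hochberg adjusted p = 8.9e-05, 1.11e-05 and 0.000158). Pf4 was 38.8 and 53.7 FPKM against 9.19 and 12.5 (1.99 ± 0.38, limma, Benjamini-Hochberg adjusted p = 0.00456), and Ppbp was 17.1 and 24.7 and 0 in both CMP libraries. The megakaryocyte and platelet list passed, with 8 of 17 genes higher and 2 lower (median 1.17, adjusted p = 0.00251, 0.663 with an estimated correlation).

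Stem cell, mast cell and division genes were lower in spleen Ter than in CMP. Cd34 (ENSMUSG00000016494, chromosome 1, 194938819 to 194961279) was 0.318 and 0.4998 FPKM against 29.3 and 30.1 (-4.45 ± 0.16, limma, Benjamini-Hochberg adjusted p = 1.45e-05). The receptor gene Kit was 0.490 and 2.91 against 22.92 and 22.97 (-3.31 ± 0.42, adjusted p = 0.000777 by limma). Of 19 stem cell genes 14 fell and 2 rose (median -1.38, or -1.37 with the floor, adjusted p = 0.00633 by camera, 0.589 with an estimated correlation). The progenitor lists did not pass: of 14 myeloid progenitor genes 7 fell and 1 rose (median -1.49, adjusted p = 0.0646), and of 17 lymphoid progenitor genes 7 rose and 4 fell (median -0.30, adjusted p = 0.174). Of 8 mast cell and basophil genes 7 fell (median -4.54, adjusted p = 0.0185, 0.658 with an estimated correlation). The basophil protease Mcpt8 was 17.9 and 1.37 FPKM against 579 and 411, the carboxypeptidase Cpa3 3.80 and 0.0453 against 120 and 85.7, and Gata2 0.540 and 0 against 32.9 and 22.3. Of 26 genes of mitosis and DNA replication 24 fell, or 25 adjusted over the list alone (median -2.74, adjusted p = 5.09e-07, 0.620 with an estimated correlation). Top2a changed by -4.00 ± 0.38 and Mcm5 by -3.75 ± 0.21 (limma log2 fold changes with SE).

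Genes of antigen presentation and immune suppression were higher in spleen Ter than in CMP. All 6 MHC class II genes rose (median 2.75 with the floor, adjusted p = 5.7e-05 by camera, 0.582 with an estimated correlation); H2-DMb2 was 201 and 226 FPKM against 3.64 and 3.79. Of 12 genes of immune suppression 8 rose (median 1.42, adjusted p = 0.00641, 0.658 with an estimated correlation), including Il10 (2.52 ± 0.27) and Cd274 (1.29 ± 0.18) in limma log2 fold changes. Macrophage and monocyte genes rose in 7 of 16 and fell in 3 (median 1.90, adjusted p = 0.0129, 0.680 with an estimated correlation); C1qb was 54.6 and 414 FPKM against 1.63 and 0.343. The MHC class I list passed (2 of 8 genes higher, median 0.60, adjusted p = 0.0343, 0.680 with an estimated correlation), but not without spleen Ter library B (0.192). Interferon-stimulated genes passed (8 of 21 higher and 1 lower, median 0.71, adjusted p = 0.0385, 0.722 with an estimated correlation), but not without spleen Ter library B (0.0902) or CMP library B (0.163), nor without a filter (0.172) or with median-of-ratios scaling (0.0579). The stress response list passed with 3 of 15 genes higher and 1 lower, or 2 and 1 adjusted over the list alone (median 0.32, adjusted p = 0.028, 0.658 with an estimated correlation). It did not pass without spleen Ter library A (0.193) or CMP library B (0.139), without a filter (0.0721), with median-of-ratios scaling (0.0579) or with quantile normalization (0.0702). Hepatocyte genes rose in 2 of 6 (median 0.95, adjusted p = 0.00165, 0.589 with an estimated correlation). In limma 1799 genes rose and 3544 fell, with a median log2 fold change of all genes of -0.39, relative to which MHC class II stood at 3.13. Rises were 33.7% of called genes, and 59.2% with median-of-ratios scaling and 46.7% with quantile normalization. Camera called 14 of 34 lists at the preset correlation and 0 with an estimated correlation, where 0 had an unadjusted p under 0.05.

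**Figure D3:**
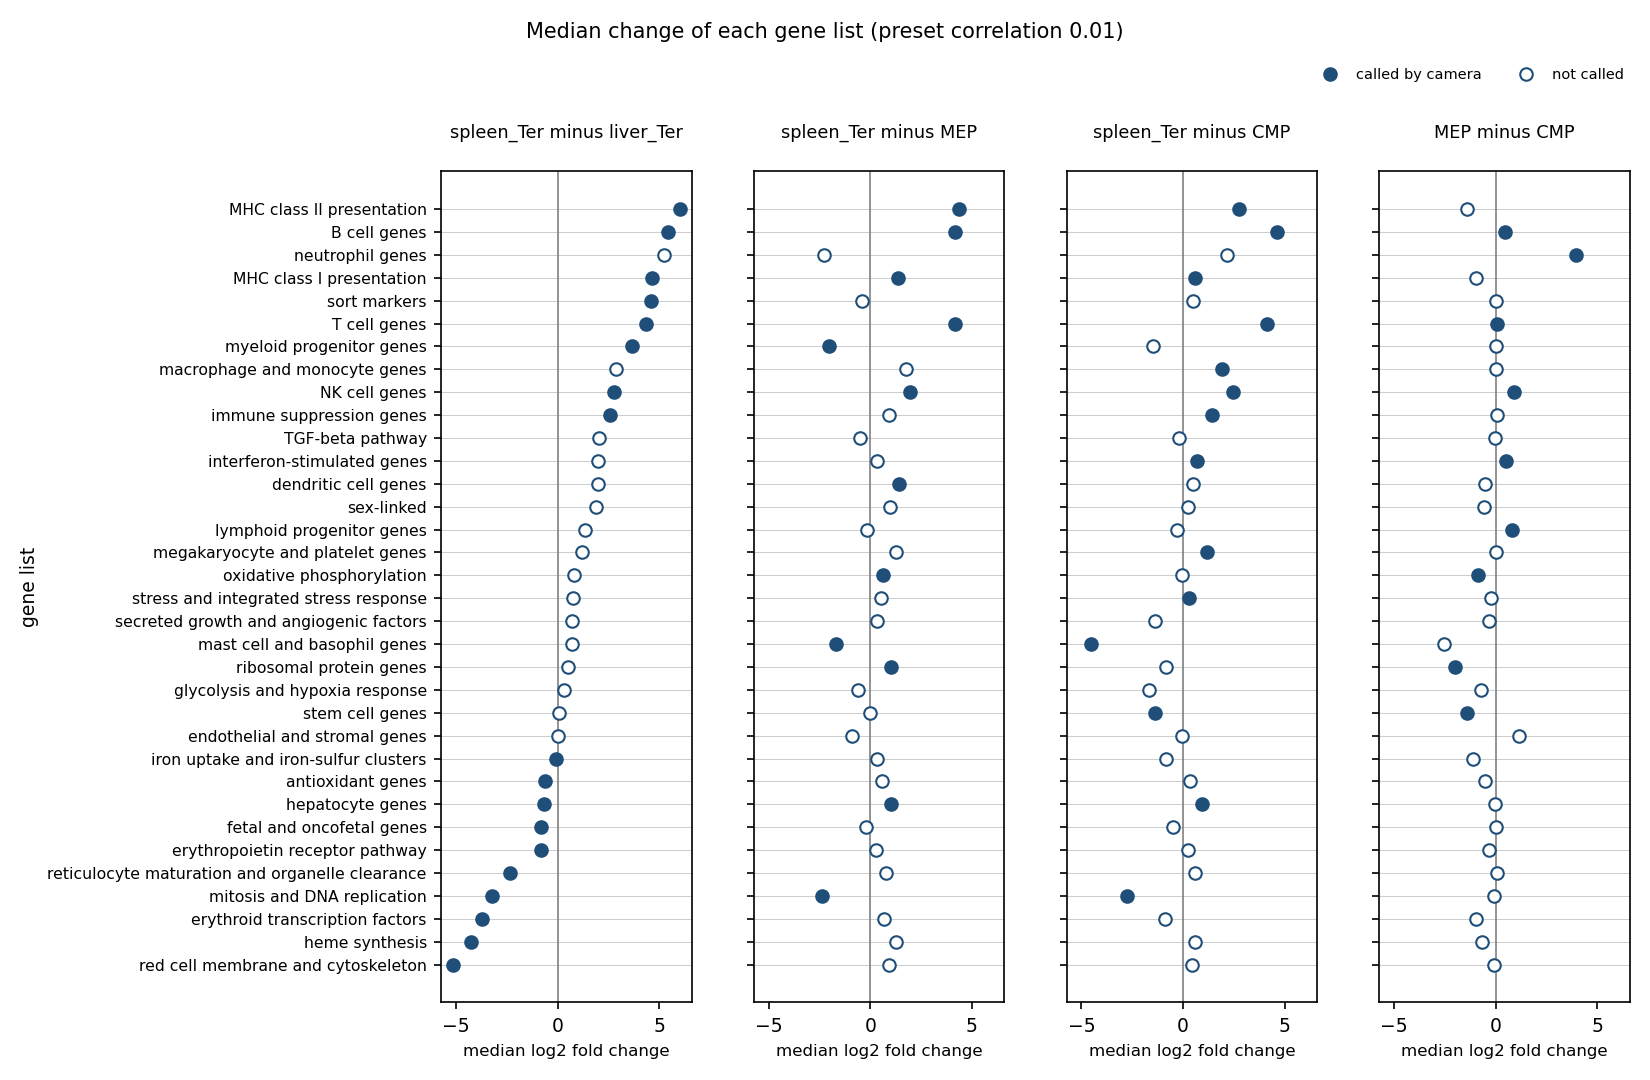
Median log2 fold change of the tested genes of each of 34 lists (horizontal axis) in the 4 comparisons tested by limma; filled points are lists that camera called at the preset correlation of 0.01. The T cell list stood at 4.37, 4.19 and 4.12 in spleen Ter against liver Ter, MEP and CMP, and the red cell membrane list at -5.16 against liver Ter. With an estimated correlation camera called 0 lists.

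Against HSC and CLP, the bone marrow stem and lymphoid progenitor populations, only the sizes of the differences between means are given. Globins were higher in spleen Ter: the mean FPKM of Hbb-bs was 22390 against 102.5 in HSC and 217 in CLP. T cell genes had medians of 3.13 against HSC and 3.09 against CLP, or 2.37 and 2.33 without library B, with 20 of 23 genes at least 2-fold higher in each; Cd8b1 was 205 and 148 FPKM in the spleen Ter libraries against 0.427 and 2.44. B cell genes had medians of 2.09 and 1.89, and MHC class II genes 2.38 and 3.29, with 9 of 10 higher in each, or 1.45 and 1.97 over the recovered genes without library B; H2-Ab1 averaged 1692 against 219 and 94.6 FPKM.

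Division, lymphoid progenitor, stem cell and mast cell genes were lower. Of 29 genes of mitosis and DNA replication 28 were at least 2-fold lower than in HSC (median -2.59) and 29 lower than in CLP (median -3.14). The proliferation antigen Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361) was 9.43 and 1.33 FPKM in the spleen Ter libraries against means of 122 in HSC and 203 in CLP. Lymphoid progenitor genes had medians of -2.52 and -2.88, with 11 and 13 of 18 genes lower; Dntt, the terminal transferase of immature lymphocytes, averaged 1.01 FPKM against 416 and 773, and Flt3 2.98 against 55.0 and 41.5. Stem cell genes were lower in 21 of 26 and higher in 2 against HSC (median -1.92), and lower in 14 of 21 against CLP (median -1.21); Cd34 averaged 0.409 against 44.4 and 15.9. Mast cell and basophil genes had medians of -4.63 and -2.60, the latter -3.67 over the recovered genes without library A, with 7 of 8 genes lower in each, and Mcpt8 averaged 9.63 FPKM against 539 in HSC and 49.0 in CLP. Over 14485 genes 2053 were at least 2-fold higher than in HSC and 4946 lower, and over 14510 genes 2247 were higher than in CLP and 5202 lower. The higher share was 29.3% for HSC, and 53.7% with median-of-ratios scaling and 50.9% with quantile normalization; for CLP it was 30.2%, 53.1% and 51.2%. The medians of all genes were -0.51 and -0.54.

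MEP and CMP were also set against each other, because the labels give a CD34+ gate for MEP and a CD34- gate for CMP. Cd34 RNA was 0.111 and 0.0273 FPKM in the MEP libraries and 29.3 and 30.1 in the CMP libraries (-4.84 ± 0.16, limma, Benjamini-Hochberg adjusted p = 0.000186). Neutrophil genes led the MEP column: S100a9 averaged 84790 FPKM against 1561 in CMP, and the neutrophil list made up 48.1% of all MEP FPKM and 1.21% of CMP. Of its 6 tested genes 5 were higher in MEP (median log2 fold change 3.93, camera, Benjamini-Hochberg adjusted p = 0.000195, 0.616 with an estimated correlation). Ly6g was 297 and 301 FPKM against 13.1 and 1.19 (5.76 ± 1.03, limma, Benjamini-Hochberg adjusted p = 0.00463), and the gelatinase gene Mmp9 was 440 and 403 against 35.5 and 2.19. Itgb2l (6.08 ± 1.13), the acute phase gene Orm1 (6.07 ± 0.75), the chitinase-like gene Chil1 (5.73 ± 0.87) and the granule glycoprotein gene Lrg1 (5.20 ± 0.67) were among the 10 largest rises, in limma log2 fold changes with SE.

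Stem cell genes were higher in CMP, as were single genes of eosinophils and monocytes. The mast cell and basophil list did not pass (5 of 8 genes lower in MEP, median -2.54, adjusted p = 0.083 by camera), nor did the macrophage and monocyte list (2 of 16 higher and 4 lower, adjusted p = 0.314). The largest differences included the eosinophil major basic protein Prg2 (-6.59 ± 0.63), the clotting factor subunit F13a1 (-5.98 ± 0.59), the monocyte and dendritic cell factor Irf8 (-4.89 ± 0.33) and the eosinophil peroxidase Epx (-4.19 ± 0.44), MEP minus CMP in limma log2 fold changes with SE. Prg2 was 2.62 and 1.01 FPKM in MEP and 314 and 212 in CMP, and Irf8 2.79 and 1.93 against 93.7 and 102. Of 19 stem cell genes 13 were lower in MEP and 1 higher, or 14 lower adjusted over the list alone (median -1.40, or -1.39 with the floor, adjusted p = 0.00185 by camera, 0.582 with an estimated correlation). Flt3 was 0.592 and 0.379 FPKM against 15.7 and 16.3, and Cd93 5.49 and 4.40 against 54.9 and 56.4. Gata2 was 3.64 and 3.78 against 32.9 and 22.3, Cebpa 9.23 and 10.8 against 67.7 and 53.3, and Cpa3 5.38 and 5.19 against 120 and 85.7. The platelet genes Itga2b (2.03 and 1.99 against 20.1 and 17.4 FPKM) and Pf4 (0.225 and 0.0691 against 9.19 and 12.5) were lower in MEP too. The megakaryocyte and platelet list had 5 genes higher and 5 lower of 17 (median 0.01, or -0.11 with the floor, adjusted p = 0.0863). The erythroid transcription factors had 1 of 17 genes higher in MEP and 6 lower and did not pass (median -0.99, adjusted p = 0.592).

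Among the other lists, ribosomal protein genes were lower in MEP in 11 of 14 (median -2.02, adjusted p = 0.000102 by camera, 0.582 with an estimated correlation). These come from the 17 recovered of 79 such genes. Over all 79 the median of the group means was 108.27 FPKM in MEP and 388.59 in CMP, which was not tested. Oxidative phosphorylation genes were lower in 8 of 23 (median -0.88, adjusted p = 0.000831, 0.582 with an estimated correlation), but with median-of-ratios scaling the median was -0.16 and the list did not pass (0.295). Atp5g1 was 5.02 and 4.58 FPKM against 21.2 and 24.3. Lymphoid progenitor genes were higher in 7 of 17 and lower in 2 (median 0.80, adjusted p = 8.85e-05, 0.658 with an estimated correlation). The surrogate light chain gene Vpreb1 was 12.01 and 12.31 FPKM against 0.737 and 0.134, and Igll1 9.29 and 10.9 against 0.695 and 0.241. NK cell genes were higher in 5 of 13 and lower in 1 (median 0.88, adjusted p = 0.00025, 0.632 with an estimated correlation), among them Il2rb. Interferon-stimulated genes were higher in 4 of 21 and lower in 1 (median 0.51, adjusted p = 0.00228, 0.676 with an estimated correlation), with a median of 0.89 under median-of-ratios scaling and 0.02 under totals that leave out globin genes. B cell genes were higher in 4 of 17 (median 0.44, adjusted p = 0.00165, 0.680 with an estimated correlation) and T cell genes in 3 of 23 (median 0.07, adjusted p = 0.00392, 0.680 with an estimated correlation, and 0.138 with median-of-ratios scaling). The T cell list had a median of only 0.22 FPKM in MEP and 0.18 in CMP. At such levels log2(FPKM + 1) hardly changes, so the list can pass because most other genes were lower in MEP. In limma 946 genes were higher in MEP and 3068 lower, with a median of all genes of -0.41, relative to which the neutrophil list stood at 4.34 and the T cell list at 0.48. Higher genes were 23.6% of called genes, and 61.2% with median-of-ratios scaling, 49.4% with quantile normalization and 10.5% with totals that leave out globin genes. Camera called 9 of 34 lists at the preset correlation and 0 with an estimated correlation, where 1 had an unadjusted p under 0.05.

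A last comparison asked which population spleen Ter cells resemble most, by Pearson's r across 12746 genes on log2(FPKM + 1), averaged over pairs of libraries, or over pairs of a spleen Ter library and a group mean. It was 0.721 ± 0.026 (SD over 2 pairs) with the CD45+ spleen control, 0.62 ± 0.005 with HSC and 0.598 ± 0.004 with CLP. With CMP it was 0.564 ± 0.020 (SD over 4 pairs), with MEP 0.541 ± 0.022 and with liver Ter 0.391 ± 0.057. Spleen Ter library A had an r of 0.441 with liver Ter and library B 0.342. No test was made, the genes are not independent replicates, and a correlation with a group mean is not like one with a single library.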

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

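The alternatives limma-voom on recovered fragments and protein-coding genes only were chosen after the results were seen; the other settings were planned. No paired analysis was possible because the recovered libraries carry no replicate numbers, so the planned replicate block was not run; nor was the planned test for counts, since the file holds none, nor leaving out samples of the control, HSC and CLP, whose libraries were not recovered.

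The scaling moved counts of genes; the cause was not tested. With median-of-ratios scaling 3489 genes were higher in spleen Ter than liver Ter and 3026 lower, 1747 lower than CMP, 3299 higher and 2850 lower than HSC, 3455 higher and 3053 lower than CLP, and 1792 higher and 1138 lower in MEP than CMP. With quantile normalization these were 2891 and 3012 for liver Ter, 3226 and 3113 for HSC, 3438 and 3277 for CLP, 1543 and 1580 for MEP against CMP, and 2858 genes were higher than in the control. With totals without globin genes 2439 genes were lower than in liver Ter, and 569 higher and 4860 lower in MEP than CMP.

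A filter of 5 FPKM tests fewer genes: 1939 were higher in spleen Ter than MEP, 1071 than CMP, 1088 than the control, 1235 than HSC and 1310 than CLP. Among protein-coding genes only, 1167 were higher and 2336 lower than in the control, 1101 higher than in HSC and 1230 than in CLP. The other counts of genes stayed within 1.5 times the reported ones under each setting run.

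Leaving out 1 recovered library gave 4723 to 6379 genes higher and 1370 to 1659 lower than in liver Ter, 2520 to 3853 and 2136 to 3071 for MEP, 1513 to 2271 and 3028 to 4645 for CMP, and 735 to 1005 and 2345 to 3217 for MEP against CMP. By means these ranges were 1309 to 2218 and 3348 to 4939 for the control, 1434 to 2333 and 4309 to 5938 for HSC, and 1568 to 2499 and 4505 to 6171 for CLP. Lists called ranged from 15 to 20 for liver Ter, 10 to 13 for MEP, 12 to 16 for CMP and 9 to 10 for MEP against CMP. No list changed its direction under a setting run while it was called. Without spleen Ter library A 8 called results of lists were lost over the 4 comparisons, and without library B 5. With an estimated correlation 0 lists passed in each of the 4 comparisons, and without a filter 14 passed for MEP against CMP. With a filter of 5 FPKM these lists did not pass (camera, Benjamini-Hochberg adjusted p): NK cell genes for liver Ter (0.0529) and for MEP against CMP (0.0549), myeloid progenitor genes (0.0873) and mast cell and basophil genes (0.0675) for MEP, stem cell genes for CMP (0.114) and for MEP against CMP (0.114), and macrophage and monocyte genes (0.0529) and immune suppression genes (0.114) for CMP. With median-of-ratios scaling the myeloid progenitor list (0.0615) and the mast cell and basophil list (0.082, and 0.093 with quantile normalization) did not pass for MEP, nor macrophage and monocyte genes for CMP (0.0541). The other called lists that did not pass under a setting are given in the report with their values; the cause was not tested. Among named genes, Slc4a1 against the control went from a log2 fold change of 2.76 to -0.22 without spleen Ter library A and 3.67 without library B.

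The similarity of spleen Ter moved with the genes used. Without a filter, which adds genes near 0, it was 0.819 with the control, 0.783 with HSC, 0.767 with CLP, 0.790 with CMP, 0.766 with MEP and 0.635 with liver Ter; with a filter of 5 FPKM 0.672, 0.512, 0.476, 0.369, 0.338 and 0.179. A pseudocount of 0.1 gave 0.595 for HSC, 0.584 for CLP, 0.486 for CMP and 0.493 for MEP, which puts MEP above CMP. Quantile normalization gave 0.629 for HSC and 0.604 for CLP, and Spearman's rho 0.628 and 0.613. Without 1 spleen Ter library it was 0.703 to 0.739 for the control, 0.617 to 0.624 for HSC, 0.595 to 0.601 for CLP, 0.563 to 0.565 for CMP, 0.522 to 0.560 for MEP and 0.342 to 0.441 for liver Ter. The control ranked highest and liver Ter lowest in each of these. Depth limits genes near 1 FPKM. Genes changed 2-fold were seldom called in simulated data, partly because a call needs an estimated log2 fold change of at least 1.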

Other observations

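The tests of the authors' other processing, of depth, of a lower erythroid share, of a control library under another label and of neutrophil-lineage cells in MEP were chosen after the results they measure were seen. The liver Ter column held the embryonic globins Hbb-y at 400 FPKM and Hba-x at 51.7, both listed at 0 in the other 6 columns. The nuclear receptor gene Nr4a1 was 206 and 225 FPKM in the spleen Ter libraries and 0.652 and 0.945 in the liver Ter libraries, and Ier2 was 295 and 332 against 6.29 and 5.92. In HSC Nr4a1 averaged 238 FPKM, in CLP 142 and in the control 459. Y-linked Ddx3y was 14.51 and 27.3 FPKM in spleen Ter and 1.34 and 1.43 in liver Ter, and was listed at 0 in the control, HSC and CLP. Xist averaged 22.1 FPKM in liver Ter, 19.8 in the control, 54.3 in HSC and 43.2 in CLP, and was listed at 0 in spleen Ter and CMP, so the spleen Ter and control samples also differed in the sex of the mice.

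The HSC and CLP columns were close to each other, with an r of 0.966 across genes. Both held transcripts of early lymphoid cells: Dntt averaged 416 FPKM in HSC and 773 in CLP, Rag1 40.8 and 91.4, Flt3 55.0 and 41.5, and Il7r 30.4 and 55.0. The stem cell list had a median of 3.96 FPKM in HSC, the highest of the 7 columns, and 1.49 in CLP, with 25 of its 27 genes at 1 FPKM or more in HSC. Among single genes Hlf averaged 7.45 and 1.42 FPKM, Mecom 0.973 and 0.102, Procr 2.09 and 0, and Slamf1 0.331 and 0.124, while Cd48 averaged 66.4 and 63.6. Mcpt8 averaged 539 FPKM in HSC, 495 in CMP, 49.0 in CLP and 44.6 in MEP. The 2 CMP libraries parted at genes of other lineages: Ly6g was 13.1 and 1.19 FPKM, Cd79a 4.55 and 0.461, Mmp9 35.5 and 2.19, and Igkc 49.2 and 2.52, while Cd34 was 29.3 and 30.1.

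Both spleen Ter libraries held transcripts of B cells, T cells and neutrophils, cells that a CD45- Lin- gate is meant to remove. The stated purity above 98% leaves room for some other cells, and how much of the RNA such cells would give was not measured. The authors' other processing of some columns is argued against, because the B cell list was 5.42 higher (median log2 fold change) than in liver Ter, a column of the same format. CD45+ cells of the control's makeup at one share are argued against too: list medians relative to the control ran from -1.51 for B cells to 4.48 for neutrophils in library A and from -0.86 to 3.20 in library B, gaps of 5.99 and 4.06 against spreads of 1.85 and 1.94. The neutrophil medians rest on 10 recovered genes. These ratios also cross the 2 sets of columns, and what the other procedure did to each gene was not measured. Within the control's set the neutrophil list had a median of 5.35 FPKM in the control, 71.98 in HSC and 167.5 in CLP. Of 5 lists (B, T, NK, macrophage and neutrophil), 5 had a higher median in both libraries than in liver Ter, with Igkc at 15980, S100a9 at 10970 and Cd74 at 4860 FPKM. This restates the pattern, so CD45+ cells of several types in another makeup than the control and expression of these genes by Ter cells themselves cannot be told apart. Of these genes 1 of 18, 1 of 23, 0 of 14, 4 of 23 and 1 of 15 belong to another list. The control holds 18, 23, 14, 12 and 12 of these genes at 1 FPKM or more.

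Red cell membrane and heme genes were higher in spleen Ter library A than in library B, by a median ratio of 11.3 on FPKM and 3.29 on FPKM + 1. The erythroid transcription factors were mixed, with a median log2 ratio of -0.07 and quartiles of -0.37 and 1.61 over 17 genes. Klf1 and Gata1 were higher in library A, as given above, and Tal1 was not. Depth is argued against, with a ratio of library sizes of 1.04; the test asked for a gene ratio above 4, which only FPKM met, and FPKM was chosen after 3.29 was seen. For a library of the control under another label, 4 Y-linked genes were set against the control, which lists them at 0. Their median was 14.4 FPKM in library B. But the sex-linked list had a median of 0 in HSC and CLP too, the columns of the control's procedure. The 0 may thus come from the procedure, or from female mice, because those columns also held Xist RNA. The Y-linked genes alone do not decide. Xist RNA, seen in columns of both formats, was found in the control and not in spleen Ter, as given above. Together with the Y-linked RNA in library B, this argues against a library of female control mice under another label. The control's mean does not give the sex of each of its samples. A lower erythroid share in library B would raise the other cell types alike, and B, T and NK cell genes rose by median log2 ratios of 0.55, 0.54 and 0.61. But macrophage and monocyte genes rose by 2.35 and neutrophil genes fell by 0.9, a gap of 3.25 against a spread of 1.93, a bound added after the first one, erythroid lists more than 2 apart, was missed at 1.9. Among what stays open is a lower erythroid share in library B together with another makeup of its other cells, from the mice or the sort. Other causes, such as a difference in the Ter cells themselves, were not tested.

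Neutrophil transcripts led the columns labelled MEP, and Cd34 RNA was near 0 there and 29.7 FPKM in CMP, against the gates the labels give, which are the reverse of the usual ones, so the RNA goes with the names. If the labels of MEP and CMP were swapped, the myeloid progenitor list should have a median above 0 in MEP minus CMP. It was 0.04, which meets that barely, with 4 genes higher and 5 lower (0.75 with median-of-ratios scaling, 0.30 with quantile normalization, -0.47 with totals without globin genes). The mean of that list was -0.56. The stem cell list was lower in MEP (13 of 19 genes, median -1.40), as the names would have it. Gata1 at 0.928 and Klf1 at 1.25 FPKM in MEP were below their means in CMP, 6.02 and 4.22, as a swap would have it. The erythroid transcription factor list had 1 of 17 genes higher in MEP and 6 lower (median -0.99) and did not pass. The megakaryocyte and platelet list had 5 higher and 5 lower (median 0.01) and did not pass either. The neutrophil list made up 48.1% of FPKM in MEP, which lowers the FPKM of other genes there whichever label is right. These signs are weak for that reason too. With results on both sides, a swap and a mistake in the text of the gates cannot be told apart. The recovered neutrophil genes had a median of 177 FPKM in MEP library A, the lower of the pair, and 182 in library B, against at most 18.3 in CMP. S100a9 averaged 84790, Ngp 34070, S100a8 32950 and Camp 14920 FPKM. This restates the pattern, so it does not decide whether cells of the neutrophil lineage were among the sorted MEP cells; 1 of the 15 neutrophil genes is in another list, and CMP holds 15 at 1 FPKM or more.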
